A study of Homo sapiens with 27 samples.

How the data were processed

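RNA sequencing was measured in 17 libraries of SHP77, a human small cell lung cancer cell line. The cells of 6 libraries carried shRNAs and those of 11 had been transfected with siRNAs. Per the labels' protocols, shRNA cells were selected with puromycin at 3 µg/ml for at least 3 days, and 1 µg of RNA entered a stranded total RNA kit. Per the same protocols, siRNA cells were collected after 72 hours and 500 ng of RNA entered a poly(A) kit. Reads were paired at 150 bases, per the labels. The series holds 27 samples in all, and its 10 ChIP-seq samples were not analysed here.

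The deposited signal was a normalized count per gene and library, in a separate table for each library kind. Per the submitters' processing notes, the authors used cutadapt 2.5, STAR 2.5.2b and DESeq2 with the genome build hg38. The version of DESeq2, the annotation and the counting tool were not given in the sources used here, nor whether counting used strand. Counts of overlapping genes, antisense genes, pseudogenes and close paralogs are therefore uncertain. Within each deposited column, the values were whole multiples of a single step, with 100% of them whole within a tolerance of 0.05 reads, so that whole reads were recovered as value over step. Recovered depth was 46.9 to 57.4 megareads (M) in the shRNA table and 15.5 to 50.1 M in the siRNA table. The tables listed 41748 and 34791 features. Features of non-human sequence (55 and 38) and copies of genes on the pseudoautosomal part of chromosome Y (7 and 11) were left out, which kept 41686 and 34742 human genes. A symbol was found for 98.5% of the gene IDs in each table. Gene positions came from an annotation of GRCh38.p14, the same build as hg38.

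Samples were grouped by the reagent and replicate that the labels name: shGFP (n = 2), circRMST shRNA 1 (n = 2) and circRMST shRNA 2 (n = 2), and si-control (n = 3), SOX2 siRNA 1 and 2 (n = 2 each) and NKX2-1 siRNA 1 and 2 (n = 2 each). The series text calls the replicates biological, and nothing states whether they were separate cultures. The p-values therefore measure only the spread between these libraries, which may be partly technical. Replicates were not copies of each other: chi-square over degrees of freedom between replicates was 5.00 to 5.84 in the shRNA table and 1.52 to 5.68 in the siRNA table, where counting error alone gives about 1. Tests were run only within a table, because the tables were normalized separately.

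Genes with a mean of at least 10 normalized counts over the libraries of a table were tested, 19068 in the shRNA table and 16750 in the siRNA table. In R 4.3.3, limma 3.58.1 was fitted to log2 of the normalized count plus 1, with a mean per group, all libraries of the table in the fit, and eBayes with a trend. Each knockdown was the average of its 2 reagents minus the control. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and all tests were two-sided. Fold changes are on that log2 scale, which understates the change of low genes. Genes were also counted where each reagent alone passed with the same sign. Fold changes of the knockdowns were correlated across genes, which are not independent replicates, so no p was given. For comparisons that share control libraries, unchanged groups were simulated against the same controls in 20 draws. No gene changed in these draws, so few or no adjusted calls arise by design. Their call counts cannot tell how many joint calls the shared controls add beside real changes.

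The genes named were fixed by rule. The targeted genes came first, with NEUROD1, POU2F3 and YAP1. For each knockdown, the rule then took the 8 genes with the largest rise and the 8 with the largest fall. These had to pass on average and with each reagent alone in the same direction, have every knockdown library beyond every control library, carry a symbol and have a mean of at least 50. From each gene list it took up to 3 members that passed with the largest change. Some genes that the rule took are not reported here. The 24 lists were neuroendocrine markers, non-neuroendocrine markers, lineage transcription factors, Notch pathway, YAP/TAZ targets, mesenchymal genes, epithelial genes, neuronal genes, neural progenitor and stem genes, lung epithelial genes, gastrointestinal genes, tuft cell genes, cell cycle genes, interferon-stimulated genes, class I antigen presentation, integrated stress response, unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, p53 targets, mitochondrially encoded mRNAs, ribosomal protein genes, fibroblast markers, and blood and endothelial markers. Lists with at least 5 measured members were tested with limma's camera, which compares a list with all other genes, with a preset correlation of 0.01 and then with an estimated correlation (statmod 1.5.0). Its p-values were adjusted over the lists of a knockdown. The rotation test fry, which asks whether a list's genes move on balance in a single direction, was run beside it. The p-value of fry moved with the order in which groups and libraries were entered, which was noticed after seeing the results, so fry was also run in 60 random orders. No list changed its direction among them. In the NKX2-1 comparison the calls of lineage transcription factors (adjusted p = 0.0481 to 0.0516) and ribosomal protein genes (0.0481 to 0.0522) depended on that order, 15 of 22 lists passed in every order and 5 in none. With circRMST and SOX2 knockdown no call depended on it.

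The groups, the tests, the rule, the lists and most alternatives were fixed before the data were examined. The alternatives fixed then were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, equal library totals, quantile normalization, the replicate number as a block, a robust eBayes, an absolute log2 fold change of at least 1, both reagents as 1 group, only a knockdown's own and control libraries, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. Alternatives chosen after seeing the data were a mean of at least 300, equal totals without mitochondrial and 7SL-type genes, crossed replicate numbers as a block, and most alternatives run for single named genes.

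The code was tested on simulated counts drawn from the real means and depths. In the circRMST comparison (18587 genes in the step), limma called 62.7% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 89.2% of those changed 4-fold, and 8.59% of its calls were false. In the SOX2 comparison (16382 genes) it called 82.1%, 97.0% and 100% at these folds, with 9.27% false calls. In the NKX2-1 comparison (16388 genes) it called 83.6%, 94.0% and 100%, with 4.64% false calls. These false shares exceed the threshold in the first 2 of these comparisons, and calls close to the threshold are the least certain. The shares come from a single draw per comparison, with 14, 19 and 9 false calls. Only 65 to 67 genes were changed at each fold, far fewer than were called in the real data. The false shares therefore do not carry over to the real calls.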

Results

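SHP77 is a small cell lung cancer line. RNA was sequenced after knockdown of circRMST, a circular RNA spliced from the long non-coding gene RMST, and after knockdown of SOX2 and NKX2-1, the transcription factors that the series describes as its binding partners. Total RNA was measured in shGFP controls (46.9 and 51.0 M reads, where M stands for megareads), circRMST shRNA 1 (51.0 and 54.6 M) and circRMST shRNA 2 (57.4 and 52.4 M). The mitochondrial ribosomal RNA MT-RNR2 took 40.5 to 45.4% of these reads and left 27.9 to 32.0 M. Poly(A) RNA was measured in si-control (17.5, 17.9 and 15.5 M), NKX2-1 siRNA 1 (21.8 and 50.1 M), NKX2-1 siRNA 2 (19.1 and 17.2 M), SOX2 siRNA 1 (30.7 and 17.7 M) and SOX2 siRNA 2 (18.5 and 16.1 M). Levels below are normalized counts as mean ± SD, and fold changes are log2 values with their SE from limma, averaged over the 2 reagents of a knockdown.

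The targeted genes were read in every group first. RMST (ENSG00000255794.6, chromosome 12, 97462804 to 97565035, GRCh38.p14) is annotated as a long non-coding RNA, and its table entry counts the whole gene, so it checks nothing about the circle. RMST was at 290 ± 20.1 in shGFP (n = 2), 276 ± 19.1 with circRMST shRNA 1 (n = 2) and 260 ± 35.9 with shRNA 2 (n = 2), a difference that did not pass (-0.12, SE 0.13, adjusted p = 0.478). SOX2 (ENSG00000181449.3, chromosome 3, 181711925 to 181714436) was at 1142 ± 54.0 in si-control (n = 3) and at 393 ± 5.10 and 452 ± 19.1 with its own siRNAs (n = 2 each), a fall of 2.70-fold (-1.43, SE 0.05, adjusted p = 9.85e-19). NKX2-1 (ENSG00000136352.17, chromosome 14, 36516397 to 36520232) was at 2234 ± 110.0 in si-control and at 1014 ± 78.6 and 816 ± 28.5 with its own siRNAs, a fall of 2.45-fold (-1.29, SE 0.05, adjusted p = 1.26e-17). Both siRNA targets were thus lower in all of their 4 knockdown libraries than in any control library.

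**Figure D1:**
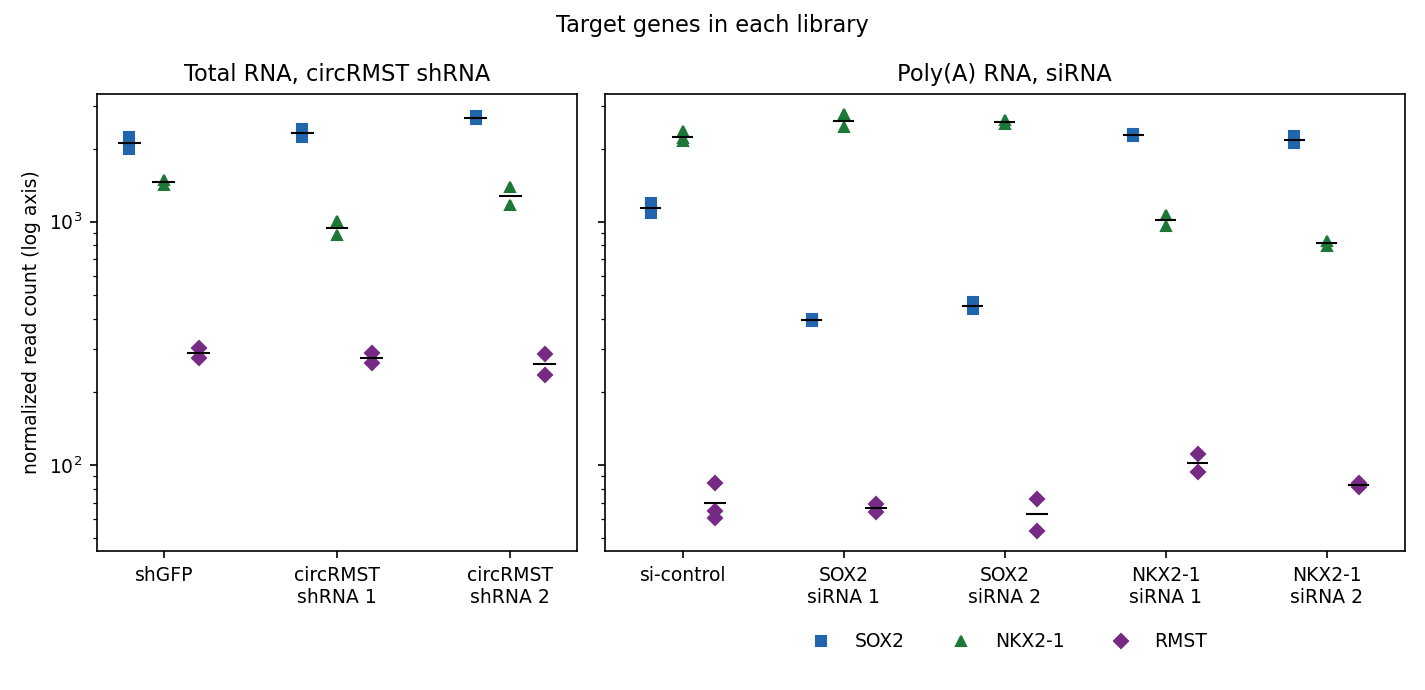
Normalized counts of RMST, SOX2 and NKX2-1 in every library, by group. Points are libraries and bars are group means; SOX2 falls from 1142 in si-control to 393 and 452 with its own siRNAs, and NKX2-1 from 2234 to 1014 and 816 with its own.

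The first comparison asked which genes depend on circRMST. NKX2-1 fell in circRMST knockdown, from 1452 ± 47.0 in shGFP (n = 2) to 943 ± 88.0 with shRNA 1 (n = 2) and 1275 ± 154 with shRNA 2 (n = 2; -0.41, SE 0.08, adjusted p = 0.000166), and with shRNA 2 alone it did not pass (-0.19, adjusted p = 0.0950). SOX2 in circRMST knockdown did not pass with shRNA 1 alone (0.14, adjusted p = 0.121). Averaged over the shRNAs it rose slightly, from 2113 ± 164 to 2322 ± 121 and 2681 ± 59.4 (0.24, SE 0.06, adjusted p = 0.00238). That call was lost with equal library totals (0.10, adjusted p = 0.208) and without shGFP replicate 1 (0.16, adjusted p = 0.0960), with adjusted p from 0.00169 to 0.208 over its 18 alternatives. NEUROD1, POU2F3 and YAP1, which mark subtypes of this cancer, had 30, 36 and 50 reads over both shGFP libraries and 2, 0 and 0 reads over the 4 knockdown libraries, too few for a fold.

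Among the largest rises, ANXA1 (ENSG00000135046.13), a phospholipid-binding regulator of inflammation, went from 13.4 ± 1.45 to 595 with shRNA 1 and 118 with shRNA 2 (4.22, SE 0.20). BEST1 (ENSG00000167995.15), a chloride channel, rose 18.3-fold, and PAPPA (ENSG00000182752.9), a protease of IGF-binding proteins, rose 14.0-fold. FGF1, a growth factor, rose 9.76-fold, the collagen gene COL14A1 9.72-fold, the peroxisomal oxidase ACOX2 9.62-fold and SLC35F3 9.10-fold. CYP1A1, a cytochrome P450 of aryl hydrocarbon receptor signaling, rose from 599 ± 41.1 to 5374 ± 830 (3.15, SE 0.06). The largest fall was that of CER1 (ENSG00000147869.4), a secreted inhibitor of BMP and Nodal, from 171 ± 7.19 to 2.14 ± 2.04 (-6.05, SE 0.67). HEPACAM2, an immunoglobulin-family gene, fell 21.3-fold from 717 ± 2.41, the secreted carbonic anhydrase CA6 27.5-fold from 335 ± 1.32, and the phosphatase regulator PPP1R17 18.1-fold from 216 ± 39.3. The pseudogene SSPOP (205 ± 103), HMCN2 (190 ± 76.2) and RADIL (134 ± 49.3) also fell, with -5.99, -4.87 and -4.24, and varied widely between the shGFP libraries. All of these 15 genes passed in limma with adjusted p of at most 4.29e-06.

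Neuroendocrine genes split in direction, while stress response genes rose nearly as a block. Of 29 measured neuroendocrine markers 10 rose and 16 fell, among them the secreted peptide gene GRP (-2.80, SE 0.07), while the reticulon gene RTN1 rose (1.35, SE 0.07). Of 17 integrated stress response genes 16 rose and 0 fell, including the transcription factors DDIT3 (2.17, SE 0.09) and CEBPB (2.30-fold) and the mTORC1 inhibitor SESN2 (1.86, SE 0.11). Camera called this list (adjusted p = 1.45e-08), but not with an estimated correlation (adjusted p = 0.159). That estimate was -0.0033, below the preset 0.01, so a higher correlation did not cost the list its call. Of 26 ribosomal protein genes 22 fell and 0 rose, with RPL19 lowest (-1.90, SE 0.06), and their camera call (adjusted p = 4.56e-08) was also lost (adjusted p = 0.502 with an estimated correlation). Of 16 unfolded protein response genes 10 rose, such as the chaperone CANX (0.87, SE 0.04), and 5 fell, such as CALR (-1.15, SE 0.05). Of 15 p53 targets 8 rose, including GDF15 (2.48, SE 0.10) and the cell cycle inhibitor CDKN1A (1.21, SE 0.07), and 3 fell, which became 7 and 5 with equal totals, where the median went from 0.16 to 0.014. Among 25 cell cycle genes 11 rose and 8 fell, with the mitotic regulator FOXM1 down (-1.35, SE 0.07) and CCNE1 up (0.85, SE 0.10), and the list's median of 0.09 turned to -0.05 with equal totals. Of 19 hypoxia and glycolysis genes 12 rose and 3 fell, NDRG1 most (-2.10, SE 0.08). Of 21 cholesterol synthesis genes 6 rose and 6 fell, including the transcription factor gene SREBF2 (-1.05, SE 0.08), and the counts became 3 and 12 with equal totals, 5 and 11 with quantile normalization and 6 and 10 with equal totals without mitochondrial and 7SL-type genes. Of 13 mitochondrially encoded mRNAs 2 rose and 7 fell.

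Lineage genes went in both directions, in numbers that moved with the scaling. Of 16 measured lineage transcription factors 6 rose and 8 fell, with MYCL, a MYC family gene amplified in some small cell lung cancers, down 4.86-fold, and with equal totals 2 rose and 8 fell. In the Notch pathway 6 of 18 rose and 7 fell, including the inhibitory ligand DLK1 (-2.87, SE 0.31), and with equal totals 3 rose and 10 fell. Of 16 YAP/TAZ targets 8 rose and 3 fell, and the LIM protein gene AJUBA rose 4.86-fold, while with equal totals 7 rose and 5 fell. Non-neuroendocrine markers rose in 8 of 14 and fell in 4, ANXA1 among the former. Mesenchymal genes rose in 4 of 17 and fell in 7, with fibronectin FN1 down 4.88-fold (-2.29, SE 0.07), and epithelial genes rose in 4 of 12 and fell in 6, such as the protease ST14 (-1.80, SE 0.25), which became 1 and 7 with equal totals. Of 25 neuronal genes 14 rose and 8 fell, among them the splicing factor gene RBFOX3 (-5.26, SE 0.72). The median of that list was 0.46, its mean -0.045 and its camera test upward (adjusted p = 0.0375, and adjusted p = 0.502 with an estimated correlation of 0.0046, also below the preset). Of 14 neural progenitor and stem genes 3 rose and 8 fell, PAX6 from 84.2 ± 30.5 to 2.56 ± 4.45. Of 10 lung epithelial genes 3 rose and 4 fell, where the median (-0.40) and the tests (upward) differed in sign and the tight junction gene CLDN1 rose 6.63-fold. Gastrointestinal genes fell in 5 of 8 and rose in 1, including the mucin gene MUC6 from 58.8 ± 21.4. All 6 measured tuft cell genes fell, such as VIL1 (-2.90, SE 0.33), a camera call (adjusted p = 0.0375) that was lost (adjusted p = 0.502 with an estimated correlation). Of 22 interferon-stimulated genes 6 rose and 4 fell, with the list's median of 0.14 at -0.0017 with equal totals (4 higher and 4 lower) and at 0.37 with quantile normalization (9 and 4). Class I antigen presentation rose in 4 of 11 and fell in 2, with the peptidase gene ERAP1 up (1.07, SE 0.08). Of 5 fibroblast markers 1 rose, LUM (2.34, SE 0.13), and 3 fell. Of 2 blood and endothelial markers 1 fell, PECAM1 by 2.30-fold, and the median turned upward with quantile normalization. Of 23 lists tested, camera called 4 with the preset correlation and 0 with an estimated correlation, and fry called 19. Among these 4, the estimate exceeded the preset for ribosomal protein genes (0.518) and tuft cell genes (0.204). It lay below the preset for the stress response and neuronal lists. The loss of all 4 calls therefore does not show that correlation between genes caused it, and its cause was not tested. Adjusted over the list alone, 18 of the 24 lists gave the same counts. The exceptions had 8 lower in the Notch pathway, 4 lower in YAP/TAZ targets, 9 lower in stem genes, 5 higher and 3 lower in interferon-stimulated genes, 3 lower in class I genes and 4 lower in hypoxia genes.

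The shGFP libraries held more low-level reads than the knockdown libraries. Of 1548 protein-coding genes without a read in the siRNA libraries, 82.4% and 85.6% had a read in the shGFP libraries, against 14.7 to 20.5% in the knockdown libraries. Genes without a read in any shRNA library were not listed, so each of the 1548 had a read in some shRNA library. This raises the shares and the excess below, and does not change which group held more. The shGFP excess of the 1548 genes had a median of 4.03 and a 99th percentile of 38.7 normalized counts. NEUROD1, POU2F3 and YAP1 lay within that percentile, at shGFP means of 14.9, 18.0 and 24.9. Of the genes that fell, 1105 of 4936 lay within that percentile. Within the lists this held for 4 of the 6 fallen tuft cell genes, 3 of 8 stem genes, 2 of 8 neuronal, 2 of 7 mesenchymal, 2 of 4 lung epithelial, 2 of 3 fibroblast, 1 of 5 gastrointestinal, 1 of 6 epithelial, 1 of 4 non-neuroendocrine and 1 of 4 interferon-stimulated genes. It held for none of the fallen neuroendocrine, lineage, Notch, cell cycle or ribosomal protein genes. Each of the 7 large falls named above exceeded the percentile, by 3.21 to 17.5 times. Only those of CA6 and HEPACAM2 (excess of 321 and 677) also exceeded the largest excess of a silent gene, 271. Silent means here only without a read in the poly(A) siRNA libraries. Single silent genes had up to 1406 reads in shGFP replicate 2 and up to 2143 in circRMST shRNA 2 replicate 1. The percentile and the largest excess are therefore not limits of background alone. The share of reads on RN7SL genes also moved with the group, from 0.186% and 0.180% in the shGFP libraries to 0.379 to 0.467% in the 4 knockdown libraries.

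**Figure D2:**
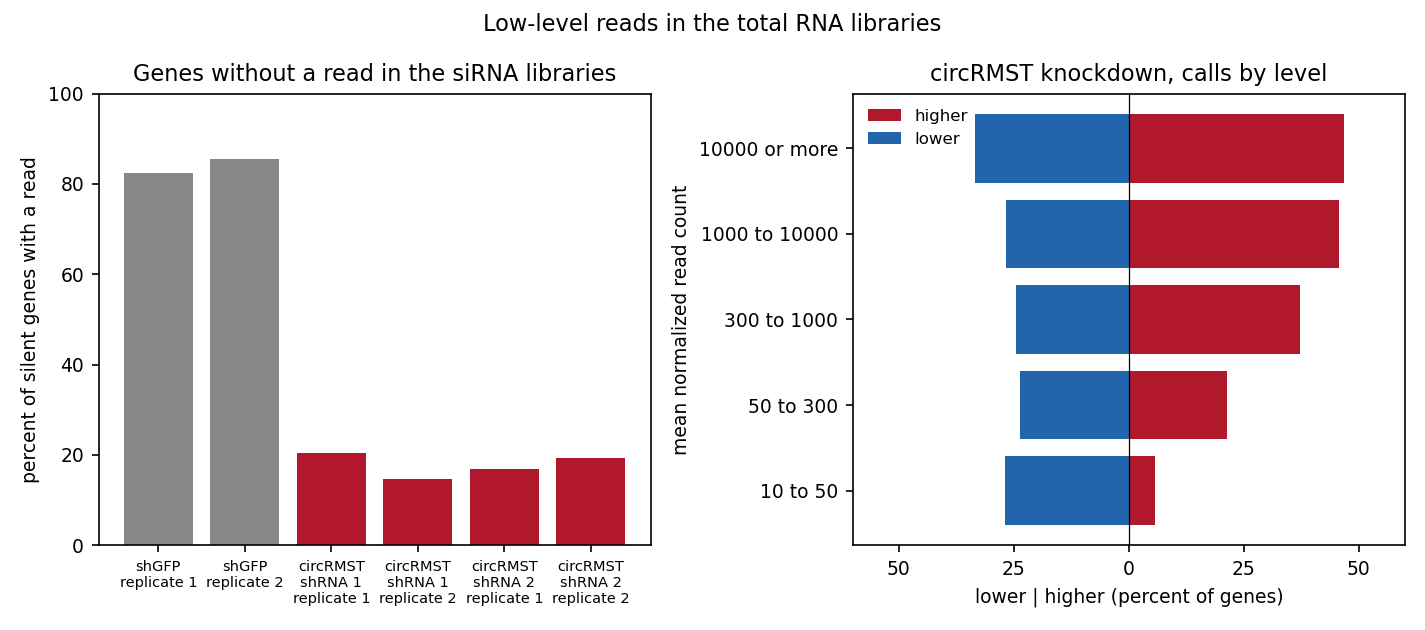
Low-level reads in the shRNA libraries, by library and group. Of 1548 protein-coding genes with a read in some shRNA library but none in the siRNA libraries, 82.4% and 85.6% hold a read in the shGFP libraries and at most 20.5% in any circRMST knockdown library.

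Of 19068 genes tested, 5294 rose and 4936 fell in limma, 830 and 2062 of them at least 2-fold. The fold changes of the shRNAs correlated across genes (r = 0.88), which are not independent replicates, against 0.50 simulated for unchanged groups with the same controls. Their covariance was 0.921 against 0.0617 simulated. Both shRNAs raised 3742 genes and lowered 3309, against 1248 and 1059 for independent lists, and 99 went opposite ways. The simulation, in which no gene changed, gave at most 2 joint calls. Every knockdown library lay beyond every control library for 56.7% of genes, where chance gives 13.3%. The split moved to 4707 higher and 10409 lower over 41686 genes with no filter, to 3635 higher and 6588 lower with equal totals, which shift the median of all genes by -0.15, and to 4251 higher and 2616 lower among genes with a mean of at least 300, a limit chosen after seeing the data. The 2 shGFP libraries cannot be split into 2 parts of at least 2, so part of the excess between the shRNAs may come from these shared controls.

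The second comparison asked which genes depend on SOX2. Most cell cycle genes (22 of 25) and cholesterol synthesis genes (16 of 22) rose with SOX2 siRNA. Most genes of class I antigen presentation (10 of 11), interferon-stimulated genes (12 of 16), integrated stress response genes (15 of 17) and non-neuroendocrine markers (12 of 16) fell. NKX2-1 rose slightly, from 2234 ± 110.0 (n = 3) to 2605 ± 225 and 2569 ± 54.0 (n = 2 each; 0.21, SE 0.05, adjusted p = 0.000650). RMST did not pass (69.9 ± 12.5 in si-control, -0.10, SE 0.16, adjusted p = 0.616). NEUROD1 and YAP1 had 1 and 0 reads in si-control and 0 with SOX2 siRNA.

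The largest rise was that of CAP2 (ENSG00000112186.11), an actin regulator, from 24.0 ± 6.00 to 248 ± 27.9 (3.34, SE 0.18). EYA1, a developmental transcriptional coactivator, rose 6.42-fold, the chemokine receptor ACKR3 5.97-fold and the hormone gene SST 5.74-fold. PRSS56 rose 4.59-fold, ZNF469 4.49-fold, the calcium-binding protein gene CALB2 4.48-fold and the Wnt regulator DACT1 4.27-fold. SERPINA5 (ENSG00000188488.13), a protease inhibitor, fell from 73.4 ± 11.6 to 1.36 ± 1.90 (-5.30, SE 0.38). The small GTPase gene MRAS fell 15.9-fold, GP2, a glycoprotein of secretory granules, 14.4-fold from 1064 ± 38.6, and TNFSF15, a TNF family cytokine, 13.1-fold from 1316 ± 49.4. The protease inhibitor A2M fell 12.0-fold, the receptor CSF1R 9.18-fold, the Cdc42 effector CDC42EP1 8.59-fold and the phospholipase PLA2G4A 8.21-fold. All of these 16 genes passed in limma with adjusted p of at most 9.62e-11.

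Of 25 cell cycle genes 22 rose and 0 fell, by modest amounts, such as CCNA2 (0.63, SE 0.04) and FOXM1 (0.56, SE 0.05), and camera called the list (adjusted p = 0.0129 with an estimated correlation). Of 22 cholesterol synthesis genes 16 rose and 1 fell, including LSS (0.77, SE 0.04) and INSIG1 (0.72, SE 0.03; list adjusted p = 0.0168 with an estimated correlation), while with quantile normalization 14 rose and 3 fell. Class I antigen presentation fell in 10 of 11, with the peptide transporter TAP1 (-1.60, SE 0.06) and the proteasome subunit PSMB9 (-2.71, SE 0.19). Interferon-stimulated genes fell in 12 of 16, with the RNA sensors IFIH1 (-2.21, SE 0.14) and OAS1 (-3.04, SE 0.40). Integrated stress response genes fell in 15 of 17, with ASNS (-1.13, SE 0.03) and ATF3 (-1.05, SE 0.07). Non-neuroendocrine markers fell in 12 of 16 and rose in 1, with TGFBI (-2.63, SE 0.13) and MYOF (-2.38, SE 0.09). These 4 lists kept their camera calls (adjusted p = 0.0140 each with an estimated correlation). Neuroendocrine markers fell in 16 of 29 and rose in 6, with the prohormone convertase PCSK1 (-1.36, SE 0.03) and GRP (-1.25, SE 0.03; 17 fell and 4 rose with quantile normalization), and hypoxia and glycolysis genes fell in 10 of 18 and rose in 1, with VEGFA (-0.88, SE 0.05). Both of these calls held (adjusted p = 0.0424 with an estimated correlation).

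In 5 other lists the camera call was lost. Epithelial genes fell in 9 of 12 (adjusted p = 0.0514 with an estimated correlation), the protease inhibitor SPINT1 by 2.38-fold. Unfolded protein response genes fell in 12 of 16 and rose in 3 (adjusted p = 0.0822 with an estimated correlation), HSP90B1 down (-0.62, SE 0.03) and PDIA4 up (0.67, SE 0.03). Mesenchymal genes fell in 9 of 16 and rose in 1 (adjusted p = 0.114 with an estimated correlation), the cadherin gene CDH11 by 3.02-fold. The estimate for mesenchymal genes was 0.0038, below the preset, so a higher correlation did not cost that list its call. For the other lists that lost their call here, the estimates exceeded the preset (0.052 to 0.639). Neuronal genes fell in 14 of 23 and rose in 6, GAP43 by 2.58-fold, and mitochondrially encoded mRNAs fell in all 13, MT-ND4 by -0.35 and -0.83 with the siRNAs. With quantile normalization 6 of 11 measured mitochondrial mRNAs fell and 1 rose, and their median went from -0.44 to -0.13. Both lists had adjusted p = 0.169 with an estimated correlation. Camera called none of the other lists, while fry called all 22 lists tested. Lineage transcription factors rose in 7 of 14 and fell in 3, with MYCL down 2.49-fold and a median of 0.23 beside a mean of -0.029. Notch pathway genes rose in 5 of 18 and fell in 9, NRARP by 2.43-fold, and YAP/TAZ targets rose in 3 of 15 and fell in 8, CCN2 by 3.95-fold. Neural progenitor and stem genes rose in 5 of 12, LIN28B among them (0.84, SE 0.07), and fell in 4, NES among them (-1.15, SE 0.04), with a median of 0.07 beside a downward rotation test. Lung epithelial genes rose in 3 of 10 and fell in 3, CLDN1 up 3.88-fold. Gastrointestinal genes rose in 1 of 7 and fell in 3, CDX2 by 1.53-fold, with a median of -0.08 that turned upward with quantile normalization (3 higher and 2 lower) and a mean of 0.04. Tuft cell genes rose in 1 of 5 and fell in 3, PTGS1 by 3.28-fold, and with quantile normalization 2 rose and 2 fell. The p53 targets rose in 6 of 16 and fell in 9, GDF15 by 2.32-fold. Ribosomal protein genes rose in 8 of 26 and fell in 2, RPS2 up 1.21-fold, with a median of 0.028 that turned downward with quantile normalization (7 higher and 11 lower) and with equal totals without mitochondrial and 7SL-type genes (7 and 5). Fibroblast markers rose in 2 of 4, PDGFRA 3.37-fold, and of 3 blood and endothelial markers 1 fell, PECAM1 (-1.96, SE 0.10). Adjusted over the list alone, 21 lists gave the same counts; the exceptions had 5 lower in stem genes, 13 lower in interferon-stimulated genes and 1 higher in stress response genes.

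Of 16750 genes tested, 4620 rose and 4814 fell with SOX2 siRNA in limma, 315 and 913 of them at least 2-fold, and the split moved to 5105 higher and 4353 lower with quantile normalization and to 4128 and 5240 with equal totals without mitochondrial and 7SL-type genes. Fold changes of the siRNAs correlated across genes (r = 0.84, 0.395 simulated with the shared controls), with a covariance of 0.289 against 0.0162 simulated. Both siRNAs raised 3115 genes and lowered 3225, against 1058 and 1127 for independent lists, and 169 went opposite ways. The simulation, in which no gene changed, gave 0 joint calls. Libraries did not overlap for 49.5% of genes, where chance gives 5.71%. The 3 si-control libraries cannot be split into 2 parts of at least 2, so part of the excess between siRNAs may come from these shared controls.

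**Figure D3:**
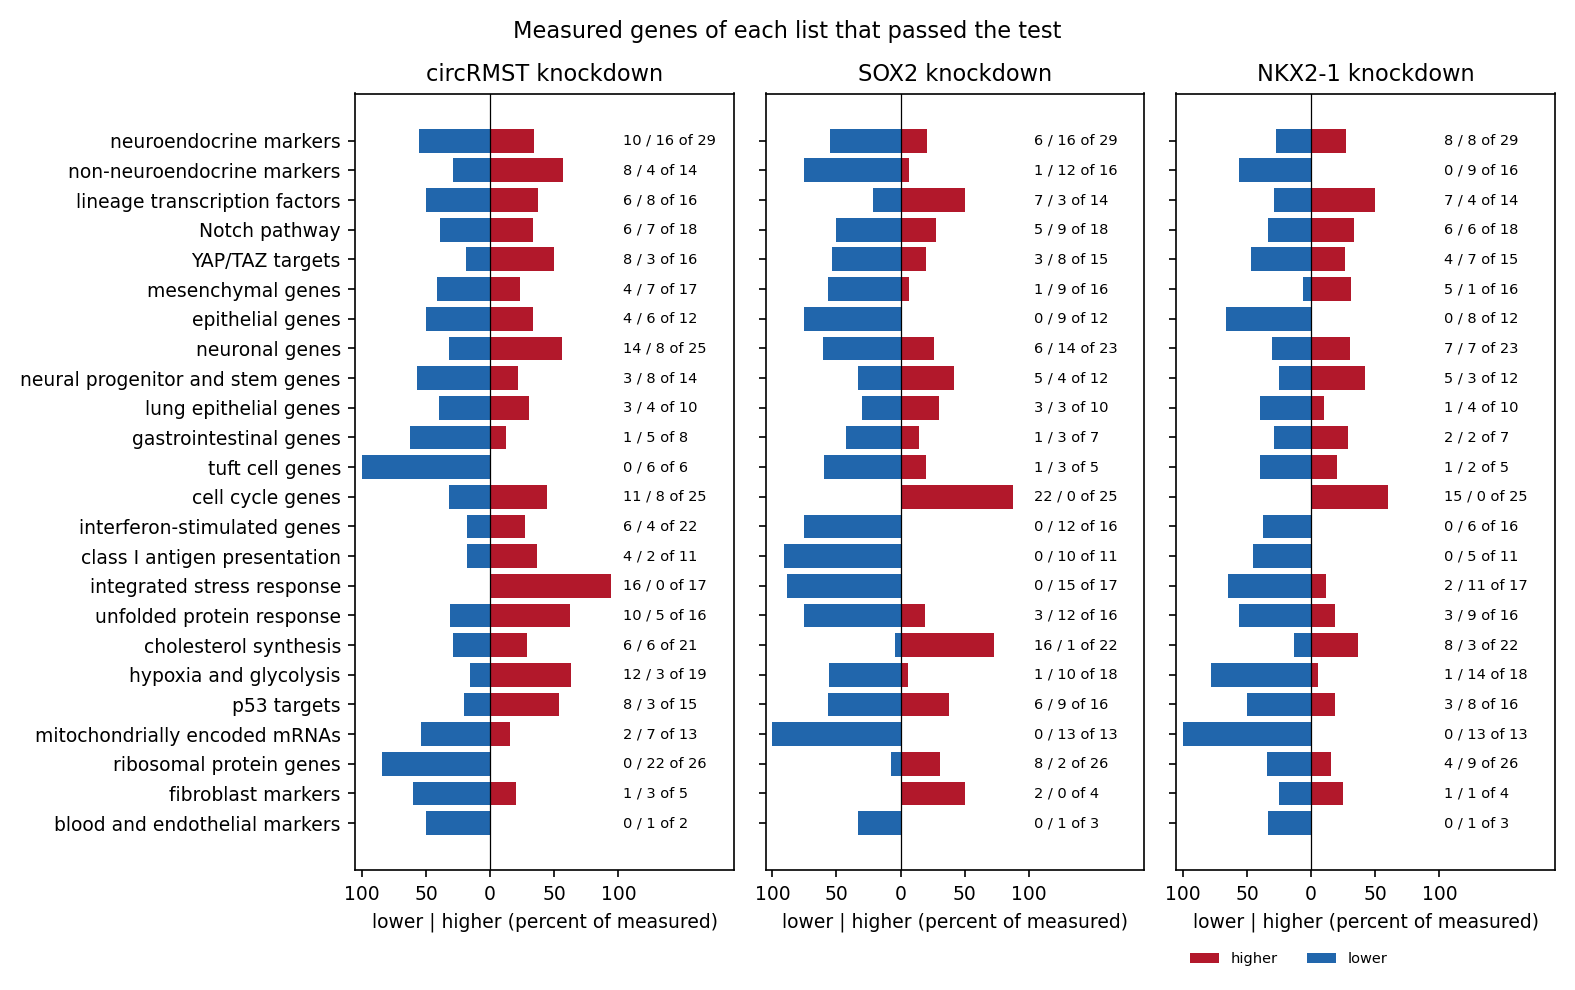
Members of each of the 24 gene lists that rose or fell in limma, as a percentage of the measured members, for each knockdown. Bars to the right are members that rose and bars to the left are members that fell; integrated stress response genes rise in circRMST knockdown (16 of 17) and fall with SOX2 siRNA (15 of 17) and NKX2-1 siRNA (11 of 17).

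The third comparison asked which genes depend on NKX2-1. SOX2 rose 1.94-fold with NKX2-1 siRNA, from 1142 ± 54.0 (n = 3) to 2263 ± 30.5 and 2175 ± 109 (n = 2 each; 0.96, SE 0.05, adjusted p = 1.43e-14). RMST in NKX2-1 knockdown was at 102 ± 12.2 and 82.5 ± 1.95 against 69.9 ± 12.5 (0.40, SE 0.16, adjusted p = 0.0496). That call was lost in 11 of 18 alternatives, whose adjusted p ranged from 0.0198 to 0.214. Among these were the fits without si-control replicate 1 or 3 (0.35 and 0.31, adjusted p = 0.140 and 0.196), without NKX2-1 siRNA 1 replicate 1 or 2 (0.34 and 0.46, adjusted p = 0.166 and 0.0540) and without NKX2-1 siRNA 2 replicate 1 or 2 (0.41 and 0.39, adjusted p = 0.0817 and 0.102). NEUROD1 had 4 reads over the NKX2-1 siRNA libraries and YAP1 3.

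The falls were larger than the rises. CEACAM6 (ENSG00000086548.8), a cell adhesion glycoprotein, fell from 211 ± 18.6 to 23.4 ± 3.69 (-3.13, SE 0.17), TNFSF15 7.11-fold and SCEL, a cornified envelope gene, 6.71-fold. The cytokine gene LIF fell 5.49-fold from 1595 ± 10.4, and the neutrophil chemokine gene CXCL8 fell 5.33-fold from 2369 ± 107, by more with siRNA 1 (-3.52) than with siRNA 2 (-1.31). TREM1, CPAMD8 and the thrombin receptor gene F2RL3 fell 5.24-fold, 5.14-fold and 5.04-fold. C3orf80 rose 3.15-fold, ERICH3 3.02-fold, LRRC53 2.93-fold and the stem cell receptor gene LGR5 2.91-fold. SLC18A1, a vesicular monoamine transporter, rose 2.80-fold, the Notch target HEY1 2.78-fold from 573 ± 13.3, the Hedgehog inhibitor HHIP 2.73-fold and CNTN5 2.69-fold. All of these 16 genes passed in limma with adjusted p of at most 5.92e-08.

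Non-neuroendocrine markers fell in 9 of 16, such as the protease PLAU (-1.25, SE 0.10). Hypoxia and glycolysis genes fell in 14 of 18 and rose in 1, with HK2 (-1.05, SE 0.10) and NDRG1 (-0.85, SE 0.04). Integrated stress response genes fell in 11 of 17 and rose in 2, with ATF3 (-0.91, SE 0.07), and cell cycle genes rose in 15 of 25, with FOXM1 (0.32, SE 0.05). These 4 lists kept their camera calls (adjusted p = 0.0473 each with an estimated correlation). Epithelial genes fell in 8 of 12, including KRT18 (-0.66, SE 0.04), and mitochondrially encoded mRNAs fell in all 13, including MT-ND5 (-0.57, SE 0.04). With quantile normalization 6 of 11 measured mitochondrial mRNAs fell and 3 rose, and their median went from -0.48 to -0.10. Both camera calls were lost (adjusted p = 0.0558 and adjusted p = 0.15 with an estimated correlation). Camera called none of the other lists, while fry called 15 of the 22 lists tested in every order of the libraries and 2 in some orders. Lung epithelial genes fell in 4 of 10 and rose in 1, with the surfactant gene SFTPB, a known NKX2-1 target, down 10.1-fold from 42.2 ± 10.0. Neuroendocrine markers rose in 8 of 29 and fell in 8, PCSK1 and the calcitonin gene CALCA down 2.54-fold and 2.07-fold, with a median of -0.012 that turned upward with both scalings to equal totals. Lineage transcription factors rose in 7 of 14 and fell in 4, REST by 2.11-fold, with a median of 0.17 beside a mean of -0.015. In the Notch pathway 6 of 18 rose and 6 fell, HEY1 up and HEY2 down 1.85-fold, with a downward camera test and an upward rotation test. YAP/TAZ targets rose in 4 of 15 and fell in 7, MYOF by 2.27-fold, which became 6 and 7 with equal totals. Mesenchymal genes rose in 5 of 16 and fell in 1, FN1 up 2.30-fold.

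Neuronal genes rose in 7 of 23 and fell in 7, NEFM by 1.82-fold, with a median of 0.00066 beside a mean of -0.0070. Neural progenitor and stem genes rose in 5 of 12, SOX21 1.98-fold, and fell in 3, NES and LIN28B by 2.40-fold and 2.36-fold, with a median of 0.15 beside a downward rotation test. Gastrointestinal genes rose in 2 of 7, PDX1 1.70-fold, and fell in 2, with a median of -0.08 beside a mean of 0.12. Tuft cell genes rose in 1 of 5 and fell in 2, PTGS1 by 1.77-fold, with a median of 0.08 beside a downward test. Interferon-stimulated genes fell in 6 of 16, OAS1 by 3.20-fold, and class I antigen presentation fell in 5 of 11, TAP1 by 1.39-fold. Unfolded protein response genes rose in 3 of 16, PDIA4 1.74-fold, and fell in 9, DNAJB9 by 1.53-fold. Cholesterol synthesis genes rose in 8 of 22, LSS 1.36-fold, and fell in 3, which became 9 and 1 with equal totals. The p53 targets rose in 3 of 16 and fell in 8, GDF15 by 1.95-fold, and in 4 with equal totals. Ribosomal protein genes rose in 4 of 26 and fell in 9, RPL4 by 1.17-fold, with a median of -0.020 that turned upward with both scalings to equal totals (8 higher and 2 lower with all genes, 7 and 6 without mitochondrial and 7SL-type genes), and with quantile normalization 6 rose and 6 fell. Fibroblast markers rose in 1 of 4, PDGFRA 2.42-fold, and fell in 1. Of 3 blood and endothelial markers 1 fell on average, PECAM1, with -1.31 for siRNA 1 and 0.29 for siRNA 2. Adjusted over the list alone, 16 lists gave the same counts. The 8 exceptions had 8 higher and 5 lower in lineage factors, 8 lower in the Notch pathway, 5 higher in YAP/TAZ targets, 2 lower in mesenchymal genes, 16 higher and 1 lower in cell cycle genes, 6 lower in class I genes, 2 higher in hypoxia genes and 5 higher in ribosomal protein genes.

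With NKX2-1 siRNA 3092 genes rose and 3592 fell in limma, 192 and 280 of them at least 2-fold, and the split turned to 4225 higher and 2643 lower with equal totals. Fold changes of the siRNAs correlated across genes (r = 0.68, 0.397 simulated with the shared controls), with a covariance of 0.125 against 0.0162 simulated. Both siRNAs raised 1487 genes and lowered 1713, against 468 and 631 for independent lists, and 298 went opposite ways. The simulation, in which no gene changed, gave 0 joint calls. Libraries did not overlap for 33.9% of genes, where chance gives 5.71%. As for SOX2, part of the excess between siRNAs may come from the shared controls.

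The last comparison asked whether circRMST, SOX2 and NKX2-1 act on shared genes. SOX2 and NKX2-1 siRNAs changed 3693 genes in the same direction, against 1885 for independent lists. The simulation, in which no gene changed, gave at most 1. In opposite directions SOX2 and NKX2-1 siRNAs changed 1018 genes, against 1879 for independent lists. The chemokine gene CXCL8 fell with both (-1.94 and -2.41), as did TNFSF15 (-3.72 and -2.83), and the receptor tyrosine kinase gene MET rose with both (1.42 and 1.41). CALB2 rose with SOX2 siRNA and fell with NKX2-1 siRNA (2.16 and -2.17). Across genes, which are not independent replicates, r was 0.46 against 0.575 simulated for unchanged groups with the shared controls, and the covariance was 0.103 against 0.0164 simulated, a difference of 0.0867. The 3 si-control libraries cannot be split, so part of the excess may come from them. Between circRMST and SOX2 knockdown r was -0.0116 over 15846 genes tested in both tables, with 2690 genes changed in the same direction (2667 for independent lists) and 3142 in opposite directions (2677). Between circRMST and NKX2-1 knockdown r was -0.0223, with 2007 in the same direction (1882) and 2292 in opposite directions (1909). SCEL, for example, rose in circRMST knockdown (2.49) and fell with SOX2 siRNA (-2.09) and NKX2-1 siRNA (-2.75), while NDRG1 fell in all of them (-2.10, -0.88 and -0.85). The library kinds, depths and times differed between the tables, so these fold changes come from different preparations.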

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

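In this part, the tests of the shared controls, of the control siRNA and of other splits of the libraries were chosen before their results were seen, and the direct contrasts between knockdowns and between reagents were not among the comparisons fixed beforehand.

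The SOX2 and NKX2-1 knockdowns differed from each other in 9354 genes by limma's direct contrast. All 1018 genes called in opposite directions against si-control also passed in that contrast, which opposite calls against the same controls make nearly certain. The largest such difference among the genes named was that of MRAS, which fell with SOX2 siRNA and rose with NKX2-1 siRNA (-3.99 and 1.66), a difference of -5.65 (SOX2 minus NKX2-1 siRNA, log2, SE 0.30, adjusted p = 4.69e-15). CALB2 went the other way, with a difference of 4.33 (SE 0.13, adjusted p = 2.73e-20). GP2, which fell with SOX2 siRNA and stood at 0.26 with NKX2-1 siRNA, differed by -4.11 (SE 0.08, adjusted p = 4.84e-24). The monoamine transporter SLC18A1 differed by -2.53 (SE 0.09, adjusted p = 8.86e-19), and the Notch target HEY1 by -2.11 (SE 0.05, adjusted p = 4.65e-22). The targets differed as well, SOX2 by -2.39 (SE 0.05, adjusted p = 4.84e-24), from -1.43 with its own siRNAs and 0.96 with NKX2-1 siRNA, and NKX2-1 by 1.51 (SE 0.05, adjusted p = 3.86e-20), from -1.29 with its own siRNAs and 0.21 with SOX2 siRNA. The reagents of a knockdown also differed from each other, in 3639 genes for the circRMST shRNAs, 3094 for the SOX2 siRNAs and 4447 for the NKX2-1 siRNAs.

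Against these differences, 3693 genes changed in the same direction with SOX2 and NKX2-1 siRNA. Chance values of the shared si-control libraries are argued against as the whole cause, since the covariance of the fold changes was 6.10 times the highest simulated one. An effect of the control siRNA and a response shared by both knockdowns cannot be told apart for these genes, because only si-control served as control. In the direct contrast 52.4% of them (1936) differed in size, which was to count against the control siRNA alone, but that contrast called 55.8% of all genes, and an effect of the control together with a separate effect of a single knockdown gives the same. Of the remaining 1757 genes, 40.6% changed alike with all 4 siRNAs, which either would give.

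For the number of changed genes with SOX2 siRNA against si-control, other splits of the 7 libraries argue against chance in the grouping but cannot exclude it. The real split gave 7467 genes in limma and the highest of the other splits 0, so that 1 of 35 splits gave as many, and at an unadjusted p under 0.05 the values were 8672 and 5245. For NKX2-1 siRNA against si-control the same holds, with 3522 genes in the real split and 0 in the highest other. There too 1 of 35 splits gave as many, with 5859 and 3785 genes at an unadjusted p under 0.05. That share of 2.86% is the lowest that 35 splits can give. All other splits mix control and knockdown libraries, so an effect enters their spread and lowers their counts. The splits also take the libraries as independent, which nothing states.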

How the results depend on the processing

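In this part, the alternatives chosen after the results were seen were a mean of at least 300, equal totals without mitochondrial and 7SL-type genes, crossed replicate numbers and most alternatives for single genes. The counts of changed genes stayed within 1.5 times their value under all alternatives run except the ones named here, from 6867 to 15116 for circRMST, 6384 to 9458 for SOX2 and 4913 to 7260 for NKX2-1 knockdown. An absolute log2 fold change of at least 1, which by construction keeps fewer genes, left 2892 genes for circRMST (1922 with both shRNAs), 1228 for SOX2 (845 with both siRNAs) and 472 for NKX2-1 knockdown (240 with both siRNAs). With both NKX2-1 siRNAs as 1 group of 4 libraries 3277 genes passed, where differences between the siRNAs count as spread. Genes called by edgeR were 10200, 9276 and 6710, and by DESeq2 9161, 8318 and 5608. The correlation of circRMST with SOX2 fold changes moved from -0.0116 to -0.0800 with a mean of at least 50, -0.136 with a mean of at least 300, -0.0562 with quantile normalization and -0.0475 as Spearman's rho. That of circRMST with NKX2-1 moved from -0.0223 to -0.0709 with a mean of at least 50 and -0.0756 with a mean of at least 300, and that of SOX2 with NKX2-1 from 0.465 to 0.537 with no filter. For these correlations the cause was not tested. Leaving out each library gave 7727 to 9817 genes for circRMST (5210 to 6354 with both shRNAs), 8590 to 9288 for SOX2 (5268 to 6005 with both siRNAs) and 5688 to 6073 for NKX2-1 (2356 to 2778 with both siRNAs), with correlations from -0.0204 to -0.00279, -0.0289 to -0.0154 and 0.452 to 0.487. In these fits a lone library was assumed to vary like the other groups. Replicate numbers did not pair the libraries: same-numbered libraries of different groups had correlations of deviations from -0.126 to 0.0999 in the shRNA table and -0.353 to 0.0423 in the siRNA table. Differently numbered libraries reached 0.126 and 0.353. Between groups of 2 libraries these values are by construction the negatives of the same-numbered ones, and so are no separate evidence. The value of 0.353 held for NKX2-1 siRNA 1 replicate 2 and SOX2 siRNA 1 replicate 1, the deepest siRNA libraries (50.1 and 30.7 M). It held equally for the other library of each of these groups, and its cause was not tested. With the replicate number as a block 10127, 8436 and 5401 genes passed, and with both reagents 6931, 5522 and 2606. With crossed replicate numbers as a block 10720, 8805 and 5970 passed. Of 256 results for named genes, 18 lost their call in some alternative (61 of 4595 values) and 0 reversed.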

Other observations

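In this part, the tests of background reads, of RNA from other cells and of deeper sequencing were chosen after the results were seen, as were the gene examples of the next 2 paragraphs.

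All 4 siRNAs against SOX2 and NKX2-1 raised 793 genes and lowered 845. Among the raised genes were the receptor MET (1.42 with SOX2 and 1.41 with NKX2-1 siRNA), the transcription factor MAF (1.42 and 1.34), the neuronal adhesion gene CNTNAP2 (1.23 and 1.29) and the histone gene H3-3A (1.31 and 1.30), which shares sequence with its pseudogene H3P6 so that its count is uncertain. Lowered genes included the immune receptor TREM1 (-3.01 and -2.39), TNFRSF9 (-2.69 and -2.16) and the synaptic immediate early gene ARC (-1.85 and -1.68). With all siRNAs, 150 genes rose with SOX2 and fell with NKX2-1 knockdown, such as the RNA-binding protein gene LIN28B (0.84 and -1.24) and PCP4 (1.22 and -0.70), and 111 went the other way, such as the receptor OR51E1 (-1.74 and 1.41) and PLD1 (-1.22 and 1.00).

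Over 15846 genes tested in both tables, 177 rose with every reagent of all knockdowns, 63.9 being the number for independent lists, and 155 fell (59.1). Among the latter was the neuropeptide gene NTS (-1.93 with circRMST shRNA, -0.95 with SOX2 siRNA and -0.80 with NKX2-1 siRNA). The circRMST shRNAs raised 294 genes that both siRNA pairs lowered (76.3 for independent lists), such as the neurosecretory gene VGF (1.80, -1.51 and -1.19). They lowered 185 that both siRNA pairs raised (49.5), such as BANF1 (-2.50, 0.76 and 1.15). The numbers for independent lists take the SOX2 and NKX2-1 lists as independent, though these overlap and share si-control libraries. Every class in which SOX2 and NKX2-1 siRNA agreed exceeded its number. Every class in which they disagreed lay below it, with 44 (74.2) and 40 (65.8) genes raised and 41 (57.4) and 28 (50.9) lowered by the circRMST shRNAs. An excess of these classes as such thus cannot be told from agreement of SOX2 and NKX2-1 siRNA alone. That agreement would leave the circRMST directions split as for independent lists, with more genes raised than lowered. Among genes that both siRNA pairs raised, 177 rose and 185 fell with the circRMST shRNAs, against 63.9 and 49.5. Among those that both lowered, 294 rose and 155 fell, against 76.3 and 59.1. For the larger excess of opposite changes, these values argue against agreement alone, and its cause was not tested.

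Low-level genes fell far more often than they rose in circRMST knockdown, 1442 against 299 among genes with a mean of 10 to 50, with a median of -0.41. Argued against are deeper sequencing of the shGFP libraries, which held 0.949 times the reads outside MT-RNR2, and RNA of fibroblasts, blood or endothelial cells, whose 22 markers exceeded the knockdown libraries by a median of 1.74 times that of silent genes, with COL1A2 and COL3A1 at 7.71 and 6.40 in shGFP. PECAM1 went from 361 to 156, PDGFRA from 286 to 71.4 and COL1A1 from 45.8 to 8.02, and LUM went the other way, from 110 to 587. Background reads that do not depend on transcription, such as genomic DNA, are a candidate explanation, since 157 genes of families such as olfactory receptors, chosen for having no read in the siRNA libraries, held a read 3.95 times more often in the lower shGFP library than in the highest knockdown library. It was not shown to account for all of the pattern. Of the pattern's protein-coding genes 67.2% lay within the 99th percentile of silent genes, and their median excess was 31.8 against 4.03. These values cannot decide, because silent genes were not chosen by level, while the pattern's genes needed a mean of at least 10 and a called fall. Silencing of these genes by circRMST knockdown and that background cannot be told apart, because their si-control level was 0.350 times that of uncalled genes matched on shGFP level, between the bounds set for either, and came from another library kit. Of the genes that fell, 3831 of 4936 exceeded the 99th percentile of silent genes, as did 1107 of the 2062 that fell at least 2-fold.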
